A study of Mus musculus with 12 samples.

How the data were processed

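RNA was measured in 12 libraries of hematopoietic stem cells from C57BL/6 mice, in 4 groups of 3. The groups were untreated wild type (Thpo+/+), untreated knockout (Thpo deficient), wild type given Romiplostim and knockout given Romiplostim. Romiplostim, an agonist that acts like thrombopoietin, was given intravenously at 100 µg/kg per day for 10 days, per the labels' protocols. The same protocols name PBS for the controls, while the label of those groups reads untreated. Cells were sorted by flow cytometry into TRIzol, and cDNA was amplified with a low-input kit that does not mark the strand, per the labels' protocols.

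The deposited table gives an FPKM value (fragments per kilobase of gene, scaled to the depth of the library) for every gene and library, calculated by the authors. The genome build mm10, TopHat2 and Cufflinks 2.2.1 are named in the submitters' processing notes, without their roles. No filter or annotation release is stated there. The table holds 35275 Ensembl gene identifiers, of which 34490 matched a symbol and position of GENCODE M21 on the same build and 785 did not. A total of 8754 genes were listed at 0 in all 12 libraries. No 2 of the library columns were identical.

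The depth was recovered from the values themselves, since low FPKM values of a gene fall on multiples of 1 step per library. It came to 27.7 to 35.6 M fragments per library (median 30.3 M). This check used the merged exon length of GENCODE M21, and between 48.5% and 53.3% of the values of under 50 fragments in a library were whole within 0.05. For 43.7% of the 9927 eligible genes the values were whole in all libraries checked, so that the recovered depth is an estimate. At this depth 3 fragments on a transcript of 2 kb correspond to 0.0422 to 0.0541 FPKM. Such floors cover counting error only, because the amplified reads carry no molecular identifiers.

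FPKM values were converted to log2(FPKM + 1). Genes were tested when they had an FPKM of at least 1 in at least 3 libraries, which left 12823 genes. Group means were fitted to all 12 libraries with limma 3.58.1 (R 4.3.3), with an intensity trend in its empirical Bayes step. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast, with an adjusted p under 0.05 as the criterion. The 5 contrasts were knockout against wild type without treatment, Romiplostim against no treatment in wild type, the same in knockout, knockout against wild type under Romiplostim, and the interaction, which is the agonist effect in knockout minus that in wild type. An exact comparison of 3 libraries with 3 cannot go below a p of 0.1, so only the model across genes could reach the criterion.

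The 29 gene lists covered thrombopoietin signalling, STAT5 targets, megakaryocytes, stem cell identity, quiescence, cell cycle, oxidative phosphorylation, mitochondrially encoded genes, mitochondrial biogenesis, glycolysis, fatty acid oxidation, cholesterol synthesis, stem cell ageing, interferon response, immediate early genes, p53 and apoptosis, DNA repair, unfolded protein response, autophagy and lysosome, ribosomal proteins, ribosome biogenesis and sex-linked genes. They also covered markers of erythroid, myeloid, lymphoid-primed, B, T and NK, mast and basophil, and stromal and endothelial cells. Each list was compared with the other tested genes by limma's camera with its preset correlation of 0.01 and again with an estimated correlation. For each list the members past the criterion were counted over all genes tested and adjusted over the list alone. The level of a list in a library is its mean log2(FPKM + 1).

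The contrasts, tests, lists, alternatives and the rule for named genes were written before the data were examined. The rule named Thpo first, and 3 genes that it also named are not reported here, although they stayed in every fit and list. Per contrast it then took the 10 largest rises and the 10 largest falls among genes past the criterion whose higher group had a mean of at least 5 FPKM and whose groups of 3 libraries did not overlap. The interaction had no overlap condition. Unnamed gene models, microRNA, pseudogenes and immunoglobulin or T cell receptor segments were counted but not named. At most 4 members per list, those with the smallest p, and 12 marker genes were added, namely Cish, Socs2, Pf4, Itga2b, Vwf, Selp, Cdkn1c, Mki67, Procr, Slamf1, Hlf and Mpo.

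The alternatives changed the pseudocount, the filter, the scaling, the trend, the libraries in the fit, their weights, the fold criterion and the correlation within lists, added the replicate number as a block, or left out each replicate in turn. A sex covariate, a fit without the libraries with the highest marker levels of other cell types and a blocked fit of the wild-type groups alone were added after the data were seen. Correlations between the log2 fold changes of contrasts were taken across genes, which are not independent replicates, and their standard errors came from leaving out 1 library at a time. Chance values of contrasts that share libraries were simulated 100 times with no effect, each gene drawn independently of the others.

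Whether replicate numbers pair the samples was checked by correlating the deviations of same-numbered libraries from their group means. For untreated and treated wild type the correlations were 0.40, 0.12 and 0.38, all above 0.1, and each of the 6 libraries correlated best with its own number. The highest correlation of libraries with different numbers was 0.12. Between genotypes, same-numbered libraries correlated at 0.07, −0.19 and −0.07 untreated and at −0.01, −0.12 and −0.06 treated. The labels do not say what a number stands for, so the pairing in wild type is a hint from the data. The test was checked on simulated data for the untreated comparison of genotypes with 12823 genes. It recovered 74 of 100 genes changed 2-fold and 97 of 100 changed 4-fold, and called 13 unchanged genes. A changed list had an adjusted p of 1.94e-66 with the preset and 4.81e-06 with the estimated correlation. The simulated genes were independent, whereas the correlation estimated in the data reached 0.921 for ribosomal proteins. The check therefore does not show how either list test performs on correlated genes. Data were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and the R package data.table (1.17.8), and plots were drawn with matplotlib 3.10.9.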

Results

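RNA was sequenced from hematopoietic stem cells, the cells from which all blood cells descend, sorted by flow cytometry from C57BL/6 mice. Wild-type mice were compared with mice that lack Thpo, the gene of thrombopoietin, a cytokine that acts on stem cells and megakaryocytes. Mice of either genotype were untreated or received Romiplostim, an agonist that acts like thrombopoietin, at 100 µg/kg per day for 10 days. Each of the 4 groups had 3 libraries, with a depth of 27.7 to 35.6 M fragments and 11262 to 12374 genes at an FPKM of at least 1 per library. The 3 libraries of a group shared a sequencing run, so that run and group cannot be told apart. The labels do not state that the replicates are separate animals, and the p-values then measure only the spread between these samples.

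Thpo (ENSMUSG00000022847, chromosome 16, 20724454 to 20734511, mm10) was listed at 0 FPKM in 10 of the 12 libraries, at 0.021 in untreated wild-type replicate 3 and at 0.043 in treated wild-type replicate 2. A count of 3 fragments on this gene corresponds to 0.032 to 0.041 FPKM, and to 0.040 in the last of these libraries. Since stem cells of wild-type mice also lay at the floor, Thpo does not check the genotype labels.

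The comparison of untreated knockout with untreated wild type asks what the loss of thrombopoietin changes in the RNA of sorted stem cells. Of the listed genes 22 of 27 stem cell genes were lower in the knockout, while 16 of 16 B cell, 22 of 26 myeloid, 16 of 21 erythroid and 32 of 46 cell cycle genes were higher. Each of these lists had an adjusted p of 0.352 with an estimated correlation. Ifitm1 (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), an interferon-induced membrane protein gene, had the largest fall of the named genes, from 4471 ± 604 to 198 ± 10.3 FPKM (mean ± SD, n = 3 in every group; log2 fold change ± SE −4.48 ± 0.23, adjusted p = 1.02e-06). Cd79a (ENSMUSG00000003379, chromosome 7, 24897381 to 24902197), the signalling chain of the B cell receptor, had the largest rise, from 4.95 ± 0.51 to 792 ± 335 FPKM (log2 fold change 6.95 ± 0.56, adjusted p = 8.58e-06). In all, 5779 of 12823 genes changed (45.1%), 2828 of them upward and 2951 downward, and 2252 changed at least 2-fold.

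Of the 27 genes of the stem cell identity list, 22 fell and 0 rose in the knockout (25 and 0 adjusted over the list alone), with a median log2 fold change of −1.49. The test of the list gave an adjusted p of 3.14e-10, and adjusted p = 0.352 with an estimated correlation. After Ifitm1, the members with the smallest p were Procr, the endothelial protein C receptor used to sort stem cells (−2.84 ± 0.26, 141 ± 10.3 to 18.9 ± 2.92 FPKM), Pdzk1ip1 (−2.45 ± 0.25) and Mllt3 (−1.63 ± 0.18). The transcription factor gene Hlf fell by 1.97 and the SLAM family receptor gene Slamf1 by 1.51. In the stem cell ageing list, which shares Slamf1 and Mllt3 with it, 18 of 26 members fell and 4 rose (the same counts adjusted over the list alone), with an adjusted p of 9.76e-05, and adjusted p = 0.352 with an estimated correlation. Its strongest falls by p were Art4 (−1.72), Enpp5 (−1.39), Sult1a1 (−2.76) and Plscr2 (−2.62), and the platelet adhesion genes Vwf (−1.60) and Selp (−1.79) fell.

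Among known targets of STAT5, a transcription factor activated by thrombopoietin, more fell than rose. Of 19 tested, 7 fell and 1 rose (7 and 1 adjusted over the list alone). The list as a whole did not pass (adjusted p = 0.0795, and 0.802 with an estimated correlation). The cytokine feedback inhibitors Cish (42.3 ± 14.9 to 3.78 ± 0.51 FPKM, −3.13 ± 0.32, adjusted p = 3e-05) and Socs2 (79.5 ± 23.6 to 11.3 ± 2.59 FPKM, −2.70 ± 0.31, adjusted p = 5.32e-05) fell with Ccnd2 (−1.33) and the kinase gene Pim1 (−1.88). Among megakaryocyte genes 9 of 30 fell and 3 rose, with an adjusted p of 0.467. Pf4, a platelet chemokine, had a log2 fold change of 0.44 (adjusted p = 0.547) and Itga2b, the platelet integrin chain, of 0.21 (adjusted p = 0.591). Other large falls were those of Erp27 (−3.54), the hormone receptor gene Lhcgr (−3.49), the cytokine gene Il4 (−3.39), Bdh2 (−3.15), Bex1 (−3.08), Slc24a5 (−3.02) and Wfdc2 (−3.00). Tnfsf13os, antisense to Tnfsf13, fell by 3.74, and since the kit does not mark the strand, its reads cannot be told from those of Tnfsf13 (3.83 FPKM in untreated wild type and 0.68 in untreated knockout).

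Of 46 cell cycle genes, 32 rose and 0 fell (33 and 0 adjusted over the list alone). The test of the list gave an adjusted p of 2.6e-11, and adjusted p = 0.352 with an estimated correlation. Markers of other cell types rose in the same libraries, so the cell cycle rise cannot be assigned to stem cells alone. The mitotic kinases Plk1 (2.13 ± 0.17) and Aurka (1.69 ± 0.17), cyclin Ccne1 (2.90 ± 0.28) and the nucleotide reductase subunit Rrm2 (2.38 ± 0.23) led by p. The proliferation marker Mki67 rose by 1.04 ± 0.29 (adjusted p = 0.0126), a call lost without knockout replicate 2 (adjusted p = 0.0544). Cdkn1c, a cell cycle inhibitor of quiescent stem cells, fell by 1.90 ± 0.29, while 6 of 24 quiescence genes fell and 4 rose (adjusted p = 0.917). Of 76 ribosomal protein genes, 25 fell and 0 rose (12 and 0 adjusted over the list alone; adjusted p = 1.6e-06, and 0.802 with an estimated correlation). Of 77 oxidative phosphorylation genes, 31 fell and 4 rose, adjusted over the list alone too (adjusted p = 0.000579, and adjusted p = 0.802 with an estimated correlation). The latter call was lost under quantile normalization (adjusted p = 0.0981).

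All 7 lists of other blood and stromal cells passed upward in the untreated knockout libraries, each with an adjusted p of 0.352 with an estimated correlation except the T and NK list (0.365). All 16 B cell genes rose (median log2 fold change 5.25, adjusted p = 1.29e-10), among them Fcmr (6.69), Igll1 (6.29), Vpreb3 (5.93), Vpreb1 (5.55), Blnk (5.34) and Ebf1 (5.04). Of 26 myeloid genes 22 rose and 0 fell (adjusted p = 1.12e-08), with Mpo, the neutrophil peroxidase, at 86.0 ± 47.9 and 840 ± 133 FPKM (3.48 ± 0.50) and Ly86 (4.73), Csf1r (3.65), Irf8 (3.51) and Fcgr3 (3.78) leading by p. Erythroid genes rose in 16 of 21 cases and fell in 0 (adjusted p = 1.26e-07), led by the transferrin receptor Tfrc (3.02), Rhd (4.01) and Epor (2.22). Lymphoid-primed genes rose in 10 of 15 cases (adjusted p = 6.36e-06), T and NK cell genes in 12 of 14 (adjusted p = 2.2e-06), mast cell and basophil genes in 9 of 11 with 1 fall, Il4 (adjusted p = 0.00313, but 0.0812 with a filter at 5 FPKM), and stromal and endothelial genes in 14 of 17 with 1 fall (adjusted p = 1.7e-06). The counts adjusted over the list alone were the same except for 10 mast cell and 15 stromal rises. Examples were Dntt (6.51), Cd48 (3.11), Trbc1 (4.80), Hdc (3.22) and Vcam1 (5.18), and further B-lineage genes outside the lists were Ly6d (6.45), Mzb1 (6.01) and Pou2af1 (5.36).

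The mean level of these 7 lists was 5.56 ± 0.54 log2(FPKM + 1) in untreated knockout (SD, n = 3) and 2.84 ± 0.10 in untreated wild type, beside a stem cell list level of 4.21 ± 0.19 and 5.75 ± 0.10 and a cell cycle level of 6.79 ± 0.27 and 5.75 ± 0.23. Of the 120 tested members of the 7 lists, 85 had a mean of at least 1 FPKM in untreated wild type too. Abundant transcripts of mature cells moved with them, with Igkc at 6039 ± 1600 against 58.6 ± 60.8 FPKM and C1qb at 483 ± 254 against 16.2 ± 2.52. S100a8 was at 6472 ± 6810 against 788 ± 557, with 14308 in knockout replicate 3, and Lyz2 did not pass (1662 ± 1050 against 794 ± 200, adjusted p = 0.0898). Without knockout replicate 3 and treated knockout replicate 2, the libraries with the highest level of these markers in their groups, 5820 genes changed, with 25 of 27 stem cell genes lower, 35 of 46 cell cycle genes higher and 16 of 16 B cell genes higher.

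The remaining lists did not pass in this comparison. Of 15 thrombopoietin signalling genes 4 fell and 1 rose (adjusted p = 0.928), with Pik3r1 (−0.88) and Ptpn11 (−0.59) lower and Shc1 (0.52) higher. The median of that list was 0.16 and its mean −0.11, so that its sign depends on the summary. Adjusted p-values were 0.0927 for mitochondrially encoded genes (2 of 12 fell), 0.612 for mitochondrial biogenesis (7 of 24 rose and 3 fell), 0.107 for glycolysis (7 of 25 fell and 3 rose) and 0.902 for fatty acid oxidation (6 of 22 fell and 5 rose). They were 0.917 for cholesterol synthesis (1 of 22 fell), 0.143 for interferon response (8 of 34 fell and 3 rose), 0.584 for immediate early genes (2 of 23 fell and 1 rose) and 0.174 for p53 and apoptosis (9 of 22 rose and 2 fell). They were 0.0642 for DNA repair (11 of 26 rose and 2 fell), 0.762 for unfolded protein response (3 of 23 rose and 3 fell), 0.149 for autophagy and lysosome (8 of 24 rose and 3 fell), 0.137 for ribosome biogenesis (7 of 24 rose and 1 fell) and 0.746 for sex-linked genes (0 of 5 passed). Of all 12823 genes, 56.3% had groups that did not overlap, where chance gives 10%.

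**Figure D1:**
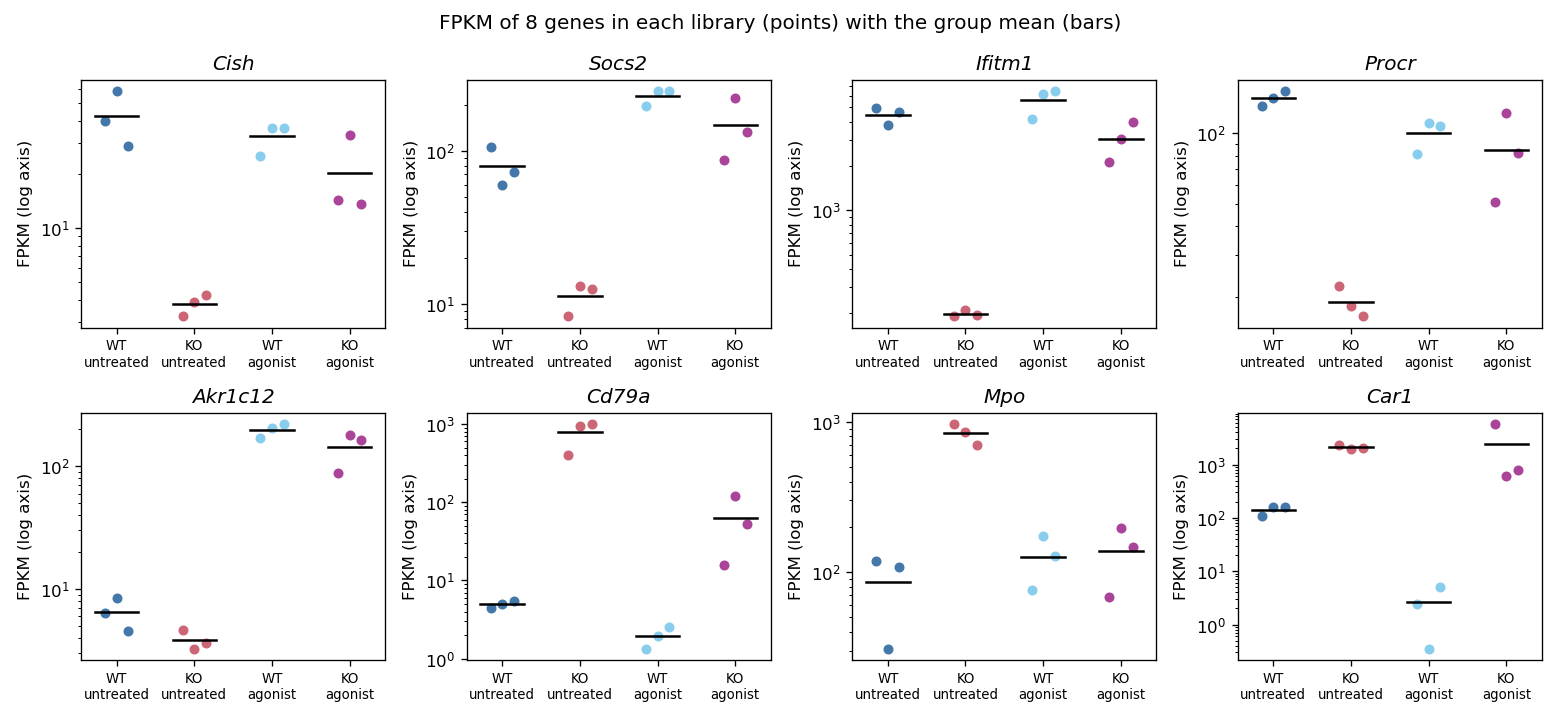
FPKM of 8 genes on a logarithmic axis, 1 panel per gene, for each of the 12 libraries (points) by group, with the group mean as a bar. Cish, Socs2, Ifitm1 and Procr lay lowest in untreated knockout, and Akr1c12 averaged 200 and 144 FPKM in the groups given the agonist and 6.45 and 3.84 in the untreated ones.

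The comparison of treated with untreated knockout asks what the agonist changes where thrombopoietin is missing. With the agonist 14 of 27 stem cell, 52 of 77 oxidative phosphorylation and 67 of 76 ribosomal protein genes were higher, and 15 of 16 B cell, 19 of 26 myeloid, 13 of 17 stromal and 20 of 46 cell cycle genes were lower. The adjusted p of these lists was 0.536 to 0.726 with an estimated correlation. Akr1c12 (ENSMUSG00000021211, chromosome 13, 4268176 to 4279433), an aldo-keto reductase gene, had the largest rise of the named genes, from 3.84 ± 0.71 to 144 ± 49.6 FPKM (4.85 ± 0.26, adjusted p = 3.57e-06). Ifitm1 rose from 198 ± 10.3 to 3049 ± 908 FPKM (3.89 ± 0.23, adjusted p = 3.96e-06). Vcam1, an adhesion molecule of stromal cells and macrophages, fell from 204 ± 95.7 to 7.21 ± 2.99 FPKM (−4.60 ± 0.36, adjusted p = 1.67e-05). In all, 3797 genes changed, 1377 upward and 2420 downward, and 1233 of them at least 2-fold.

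Of the stem cell identity genes, 14 of 27 rose and 0 fell (16 and 0 adjusted over the list alone; adjusted p = 2.02e-08, and adjusted p = 0.536 with an estimated correlation). Procr rose by 2.03 ± 0.26 to 85.0 ± 36.0 FPKM, Slamf1 by 1.53, Mllt3 by 1.23 and Tcf15 by 1.72. Hlf rose by 1.04 ± 0.28 (adjusted p = 0.018), a call lost under 6 of 18 alternatives. Of the STAT5 targets 4 rose and 4 fell (5 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.409, and 0.826 with an estimated correlation). Those with the smallest p were Socs2 (3.51 ± 0.31), Id1 (1.95 ± 0.27), Cish (2.06 ± 0.32) and Ccnd3 (−1.29 ± 0.26). The platelet gene Vwf rose by 1.89 and Itga2b fell by 0.90 ± 0.29 (adjusted p = 0.0381), a call lost under 7 of 18 alternatives. Pf4 had a log2 fold change of 0.25 (adjusted p = 0.772) and did not pass. Other large rises were those of Stxbp6 (3.56), Cox4i2 (3.55), Podxl (3.52), S100a4 (3.50), Apoa1 (3.45), Akr1c19 (3.43) and Il4 (3.23).

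Ribosomal protein genes rose in 67 of 76 cases (75 adjusted over the list alone), with a median log2 fold change of 1.06 and an adjusted p of 1.39e-22, and adjusted p = 0.583 with an estimated correlation. Oxidative phosphorylation genes rose in 52 of 77 cases and fell in 0 (59 and 1 adjusted over the list alone), with a median of 0.60 and an adjusted p of 8.48e-18, and adjusted p = 0.536 with an estimated correlation. Both directions held under median-of-ratios and quantile scaling, although quantile normalization moved the median of all genes from −0.09 to 0.07 and the share of higher genes among those changed from 36.3% to 58.2%. Mitochondrially encoded genes (1 of 12 rose, adjusted p = 0.000948, and adjusted p = 0.689 with an estimated correlation) and interferon response genes (7 of 34 rose and 1 fell, adjusted p = 0.00868, and adjusted p = 0.726 with an estimated correlation) also passed upward. Bst2 (0.72), Rtp4 (0.88) and Ly6a (1.39) were among the latter. Their list did not pass with a sex covariate (adjusted p = 0.268) or without treated knockout replicate 1 or 2 (0.0551 and 0.0565). Of the cell cycle genes, 20 of 46 fell and 1 rose (24 and 1 adjusted over the list alone; adjusted p = 0.00136, and adjusted p = 0.726 with an estimated correlation), led by Rrm2 (−1.65) and Ccne1 (−1.54). That list did not pass without treated knockout replicate 2 (adjusted p = 0.064). Autophagy and lysosome genes fell in 8 of 24 cases and rose in 2 (adjusted p = 0.0209, and adjusted p = 0.635 with an estimated correlation). The cathepsin genes Ctsd (−1.84) and Ctsb (−2.18) were among the falls.

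Lists of other cells passed downward with the agonist in the knockout, the T and NK list excepted. The B cell list fell in 15 of 16 genes (median −3.25, adjusted p = 1.73e-09), among them Fcmr (−4.36), Ebf1 (−3.65) and Pax5 (−2.62). Igkc did not pass (−0.60 ± 1.23, adjusted p = 0.744), with means of 6039 FPKM in untreated and 9315 in treated knockout and 24770 in treated replicate 3. The immunoglobulin variable segments also summed to more there than in any other library. Of the myeloid genes 19 of 26 fell (21 adjusted over the list alone; adjusted p = 5.01e-09), with Mpo at −2.72, Csf1r at −3.28 and Cd14 at −2.70. Stromal and endothelial genes fell in 13 of 17 cases (adjusted p = 1.27e-05), with Lpl at −3.50 and the chemokine Cxcl12 at −4.50. Each of these 3 lists had an adjusted p of 0.536 with an estimated correlation. Lymphoid-primed genes fell in 9 of 15 cases (adjusted p = 0.000532, and adjusted p = 0.583 with an estimated correlation). Macrophage genes outside the lists fell as well, namely C1qc (−4.18), C1qb (−4.17), Cd5l (−4.14), Fcna (−4.47) and Slc11a1 (−4.08). Erythroid genes fell in 6 of 21 cases (adjusted p = 0.0145, and 0.726 with an estimated correlation) and mast cell and basophil genes in 7 of 11 with 1 rise, Il4 (adjusted p = 0.0249, and 0.536 with an estimated correlation). T and NK cell genes fell in 3 of 14 cases and rose in 1 (adjusted p = 0.156).

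The mean level of the 7 lists of other cells was 3.82 ± 0.30 in treated and 5.56 ± 0.54 in untreated knockout, beside a stem cell level of 5.09 ± 0.47 and 4.21 ± 0.19. Without untreated knockout replicate 3 and treated knockout replicate 2, 4276 genes changed, with 11 stem cell, 75 ribosomal protein and 54 oxidative phosphorylation genes higher, but the erythroid and the mast cell lists no longer passed (adjusted p = 0.81 and 0.268), nor did they without either of these libraries alone. The labels give no sex, and the Y-linked genes averaged 11.3 to 24.9 FPKM in untreated and 0.01 to 0.04 FPKM in treated knockout libraries, where Eif2s3y fell by 5.38 ± 1.56 (adjusted p = 0.0233), a call lost under 6 of 18 alternatives. With a sex covariate 1609 genes changed, and 2021 with only these 6 libraries in the fit. Without treated knockout replicate 3 there were 2368.

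**Figure D2:**
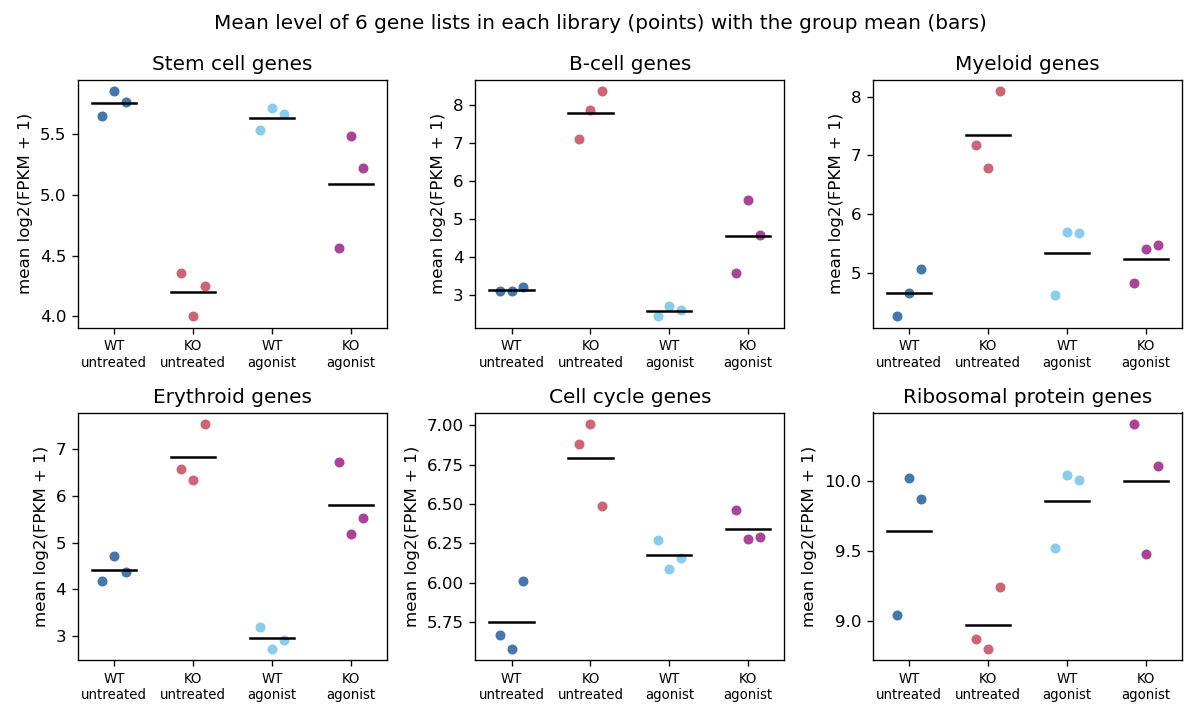
Mean log2(FPKM + 1) of the tested members of 6 gene lists in each of the 12 libraries (points) by group, with the group mean as a bar. The stem cell list averaged 5.75 in untreated wild type, 4.21 in untreated knockout and 5.09 in treated knockout, while the B cell list averaged 3.15, 7.77 and 4.56 in the same groups.

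The agonist effect in wild type asks what the drug adds where thrombopoietin is present. Akr1c12 rose from 6.45 ± 1.99 to 200 ± 25.9 FPKM (4.78 ± 0.26, adjusted p = 8.49e-06), and carbonic anhydrase Car1 (ENSMUSG00000027556, chromosome 3, 14766216 to 14808368), an erythroid enzyme gene, fell from 142 ± 28.0 to 2.60 ± 2.33 FPKM (−5.54 ± 0.72, adjusted p = 0.00285). In all, 236 genes changed, 111 upward and 125 downward, 148 of them at least 2-fold, and 1708 had an unadjusted p under 0.05. Socs2 rose by 1.54 ± 0.31 (adjusted p = 0.0258). Socs2 did not pass under 6 of 18 alternatives. Cish had a log2 fold change of −0.33 ± 0.32 (adjusted p = 0.764).

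Erythroid genes fell in 5 of 21 cases (9 with 1 rise adjusted over the list alone; adjusted p = 0.000187, and adjusted p = 0.944 with an estimated correlation). They included Rhd (−3.12) and the near-identical globin genes Hba-a1 (−4.41) and Hba-a2 (−4.44), whose reads cannot be assigned with certainty to 1 of them. The haem oxygenase gene Hmox1 (−2.88), Cldn13 (−3.14) and Slc38a5 (−2.33) fell too. The globin calls were each lost under 6 of 18 alternatives, that of Cldn13 under 4, that of Slc38a5 under 10 and that of Rhd under 1, a pseudocount of 5 (−1.60, adjusted p = 0.112). Of the cell cycle genes 8 of 46 rose and 0 fell (18 and 0 adjusted over the list alone; adjusted p = 3.38e-12, and adjusted p = 0.866 with an estimated correlation), among them Ccnb2 (1.11), Aurka (1.08), Plk1 (1.06) and Birc5 (0.95). Mki67 had a log2 fold change of 0.40 (adjusted p = 0.643). In the ageing list 4 of 26 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 0.000997, and adjusted p = 0.866 with an estimated correlation), with the sulfotransferase gene Sult1a1 at −3.73 ± 0.30 and Ehd3 at 1.28.

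The list of cholesterol synthesis passed upward with a median of 0.34 (adjusted p = 6.77e-06, and adjusted p = 0.866 with an estimated correlation), although 0 of its 22 genes passed on their own (2 adjusted over the list alone, Fdps at 0.73 and Mvd at 0.80). The T and NK list passed upward (0 of 14 genes passed, 5 adjusted over the list alone; adjusted p = 2.75e-05, and adjusted p = 0.935 with an estimated correlation). The myeloid list (adjusted p = 0.00255), ribosomal proteins (adjusted p = 5.69e-05), oxidative phosphorylation (adjusted p = 0.0171) and megakaryocyte genes (adjusted p = 0.0451) also passed upward and the B cell list downward (adjusted p = 0.0489), each with an adjusted p of 0.944 with an estimated correlation. Only Csf3r (−1.31) and Mmrn1 (−1.29) of those 5 lists passed as single genes, both downward. Igkc ran the other way from the B cell list but did not pass (58.6 to 936 FPKM, 3.74 ± 1.23, adjusted p = 0.187). The immunoglobulin variable segments summed to 23.6 to 64.7 FPKM in untreated and 153.7 to 545.2 in treated libraries. The megakaryocyte and the B cell call were each lost under 7 further alternatives, and the megakaryocyte median was −0.01 without untreated replicate 1 (adjusted p = 0.477). Without that library ribosomal proteins turned downward (−0.10). Oxidative phosphorylation did not pass under quantile normalization (adjusted p = 0.496) or without untreated replicate 2 (0.229). The stem cell list did not pass, with 1 of 27 genes higher, Ltb, and 1 lower, Rarb (adjusted p = 0.403). Its level was 5.63 ± 0.09 in treated and 5.75 ± 0.10 in untreated wild type, and that of the 7 lists of other cells 2.78 ± 0.11 and 2.84 ± 0.10.

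Other large rises in wild type were those of Stxbp6 (3.24), the leukotriene enzyme gene Alox5 (2.95), Actr3b (2.67), Ecm1 (2.62), Clec10a (2.47), Podxl (2.39), Bcas1 (2.37), Cd48 (2.28) and the STAT5 target list member Id1 (2.22), and Ccnd1 of the same list fell by 1.64 (adjusted p = 0.497 for the list). The heat shock genes Hspa1a (3.41) and Hspa1b (3.96), near-identical copies, rose too, calls that were each lost under 6 of 18 alternatives, among them the replicate block in the fit of all 12 libraries (adjusted p = 0.053 for each). The antisense gene Airn fell by 2.18, without information on strand. Leaving out 1 library left 65 to 156 changed genes, and the values were 118, 115 and 156 without untreated replicates 1, 2 and 3 and 93, 65 and 82 without treated replicates 1, 2 and 3. With only these 6 libraries in the fit 628 genes changed, and 864 with the replicate block added to that fit, which also called Procr (−0.50, adjusted p = 0.0429), Hlf (−0.79, 0.026), Cdkn1c (−0.72, 0.03), Slamf1 (0.48, 0.0431) and Itga2b (0.53, 0.027). In that fit the mast cell and basophil list passed upward (adjusted p = 0.0424) and the stromal list downward (0.0362), which had not passed in the fit of all libraries (0.0668 and 0.244, and 0.866 and 0.944 with an estimated correlation).

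The comparison of treated knockout with treated wild type asks what remains of the genotype difference once both are given the agonist. Some erythroid and B cell genes were higher in knockout. Car1 had 2400 ± 2950 FPKM in treated knockout (5804, 600 and 797 in the libraries) and 2.60 ± 2.33 in treated wild type (8.86 ± 0.72, adjusted p = 0.000308). Of the erythroid genes 9 of 21 were higher and 0 lower (16 and 0 adjusted over the list alone; adjusted p = 4.95e-23, and adjusted p = 0.318 with an estimated correlation), among them Ermap (5.66), Rhd (5.57), Sphk1 (4.95) and Hba-a2 (4.62). Means in treated wild type lay near the floor (0.06 FPKM for Ermap, 0.47 for Rhd and 0.10 for Sphk1), so that the pseudocount sets the size of these folds, from 3.55 to 8.32 for Ermap, 3.75 to 7.10 for Rhd and 2.95 to 7.40 for Sphk1 with a pseudocount of 5 and of 0.1. Cldn13 (5.38), Slc38a5 (4.89), Mt2 (4.81), Prss50 (4.70) and Tspo2 (4.51) were higher too. Plscr2, a scramblase gene of the ageing list, had the largest fall, from 38.2 ± 10.6 to 4.54 ± 0.37 FPKM (−2.79 ± 0.29, adjusted p = 0.000829), followed by Chad (−2.14), Ffar2 (−2.02), the Notch target Hes1 (−1.98), Tnfsf13os (−1.96), the platelet integrin gene Itgb3 (−1.93) and Actr3b (−1.91). In all 176 genes changed, 81 higher and 95 lower in knockout, and 2539 had an unadjusted p under 0.05.

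B cell genes were higher in 4 of 16 cases (10 adjusted over the list alone; adjusted p = 2.93e-11, and adjusted p = 0.522 with an estimated correlation), namely Cd79a (4.05), Igll1 (4.05), Vpreb3 (3.39) and Iglc2 (2.78 FPKM in wild type and 214 in knockout). The T and NK (2 of 14 higher, adjusted p = 7.81e-06), lymphoid-primed (1 of 15, adjusted p = 6.94e-05) and stromal lists (0 of 17, adjusted p = 0.000127) passed in the same direction, each with an adjusted p of 0.664 with an estimated correlation. The stem cell list passed downward with a median of −0.57 and 1 of 27 genes past the test, Hoxb5 (8 adjusted over the list alone; adjusted p = 3.75e-05, and adjusted p = 0.664 with an estimated correlation). STAT5 targets (1 of 19 lower, Pim1, adjusted p = 0.0295) and immediate early genes (1 of 23 lower, Nfkbia, adjusted p = 0.000102) also passed downward, each with an adjusted p of 0.664 with an estimated correlation. The call of the STAT5 targets was lost under 4 further alternatives, with an adjusted p of 0.251 without treated knockout replicate 1. Small upward shifts passed for cell cycle (adjusted p = 0.000206), oxidative phosphorylation (adjusted p = 1.19e-06), mitochondrial biogenesis (adjusted p = 0.0304) and ribosome biogenesis (adjusted p = 0.000141), each with an adjusted p of 0.664 with an estimated correlation, and for interferon response (adjusted p = 0.00457, and 0.71 with an estimated correlation) and ribosomal proteins (adjusted p = 0.000884, and 0.752 with an estimated correlation). Their medians lay between 0.09 and 0.16, and of these 6 lists Ccne1 (1.51) was the only gene past the test. Without treated knockout replicate 1 none of the 6 lists passed (adjusted p = 0.0532, 0.575, 0.289, 0.108, 0.0639 and 0.687 in the order given). The medians of oxidative phosphorylation and ribosomal proteins were then −0.01 and −0.05. None of the 12 marker genes passed, with Itga2b at −1.22 (adjusted p = 0.0656) and Procr at −0.30 (adjusted p = 0.529). Without treated knockout replicate 2, Socs2 (−1.07, adjusted p = 0.0311), Cish (−1.14, 0.0228) and Itga2b (−1.34, 0.0301) passed.

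The mean level of the 7 lists of other cells was 3.82 ± 0.30 in treated knockout and 2.78 ± 0.11 in treated wild type. The count of genes moved with single libraries, to 46, 31 and 42 without treated wild-type replicates 1, 2 and 3 and to 1559 without treated knockout replicate 2. Without that library and untreated knockout replicate 3 it was 1712, with 16 erythroid genes higher and 10 stem cell genes lower. Treated knockout replicate 2 led its group narrowly in the level of the 7 lists (4.05 against 3.93 in replicate 3). It also had the highest stem cell level (5.48 against 4.56 and 5.22) and the lowest erythroid level (5.18 against 6.73 and 5.53), so leaving it out widens both differences. Calls of Trim47 (−1.68), Pdcd1lg2 (−1.52) and Ctla2a (−1.66) were lost under 8, 8 and 7 of 18 alternatives, and those of Hba-a2, Mt2, Ffar2 and Hes1 under 6, 5, 4 and 4. The treated knockout libraries all carried Xist without Y-linked expression, as did 1 of the 3 treated wild-type libraries, and 38 genes changed with a sex covariate.

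The interaction asks whether the agonist effect differed between genotypes. It passed for 1996 genes, 709 with a positive and 1287 with a negative difference (log2 fold change in knockout minus that in wild type). Untreated knockout libraries carried Y-linked RNA and treated ones did not, so sex enters this difference too. Markers of other cells were highest in untreated knockout, so the cells in the sorted population may enter it as well. Ifitm1 (3.59 ± 0.33, adjusted p = 0.000369), Procr (2.53 ± 0.36), Cish (2.39 ± 0.45, adjusted p = 0.00705), Socs2 (1.97 ± 0.43, adjusted p = 0.0128) and Hlf (1.82 ± 0.40, adjusted p = 0.013) had a positive difference. The myeloid genes Ltf (−5.14 ± 1.10) and Mpo (−3.40 ± 0.71) and the lymphoid gene Ly6d (−4.88 ± 0.79) had a negative one. Of the stem cell genes 11 of 27 were positive and 0 negative (13 and 1 adjusted over the list alone; adjusted p = 2.12e-08), of the cell cycle genes 0 were positive and 21 of 46 negative (27 adjusted over the list alone; adjusted p = 6.23e-10), and of the ageing genes 6 of 26 were positive and 1 negative (adjusted p = 0.000738). Each of these 3 lists had an adjusted p of 0.446 with an estimated correlation. The cell cycle genes with the smallest p were Plk1 (−1.94), Aurka (−1.77), Rrm2 (−2.06) and Nusap1 (−1.82). Akr1c12 had an interaction of 0.07 ± 0.37 (adjusted p = 0.916).

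The lists of myeloid (15 of 26 negative, adjusted p = 4.32e-11), B cell (11 of 16, adjusted p = 9.7e-08), lymphoid-primed (7 of 15, adjusted p = 0.000114), mast cell and basophil (6 of 11 with Il4 positive, adjusted p = 0.00168, but 0.111 with a filter at 5 FPKM) and stromal genes (7 of 17, adjusted p = 8.54e-05) were negative, each with an adjusted p of 0.446 with an estimated correlation. The T and NK list was negative as well (3 of 14, adjusted p = 0.000369, and adjusted p = 0.63 with an estimated correlation). Ribosomal proteins (1 of 76 positive, Rpl5, adjusted p = 1.68e-11, and adjusted p = 0.64 with an estimated correlation), oxidative phosphorylation (10 of 77, adjusted p = 1.22e-10, and adjusted p = 0.475 with an estimated correlation), mitochondrially encoded genes (0 of 12, adjusted p = 0.0117, and adjusted p = 0.693 with an estimated correlation) and interferon response (5 of 34, adjusted p = 0.0012, and adjusted p = 0.691 with an estimated correlation) were positive. Autophagy and lysosome genes were negative in 5 of 24 cases and positive in 1 (adjusted p = 0.0391, and adjusted p = 0.64 with an estimated correlation). That call was lost under 6 further alternatives and that of the mitochondrially encoded genes under 4. Adjusted over the list alone, 0 ribosomal protein, 0 oxidative phosphorylation and 6 interferon response genes were positive, the last with 1 negative. Negative on that count were 24 myeloid, 15 B cell, 9 lymphoid-primed, 8 mast cell and basophil, 9 stromal and 6 T and NK genes. The erythroid list did not pass (adjusted p = 0.74), with Car1 (4.96) positive and Gata1 (−1.84) negative. The count was 1312, 1215, 1096, 1088 and 1192 without untreated wild-type replicate 3, treated wild-type replicates 1, 2 and 3 and treated knockout replicate 3, and 936 with a sex covariate. The calls of Vwf (1.45), Camp (−3.98), Cdkn1c (1.48) and Itga2b (−1.43) were lost under 12, 11, 9 and 9 of 23 alternatives.

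Across the 12823 genes, the log2 fold change of the agonist in knockout ran against that of the genotype in untreated mice, with a correlation of −0.83 ± 0.07 (Pearson, SE; Spearman −0.81) and a covariance of −0.59. Both share the untreated knockout libraries. In 100 simulations of independent genes with no effect, this alone gave −0.50 (between −0.55 and −0.44) and a covariance of −0.031. The difference in covariance was −0.56. Errors shared between genes were not simulated, so that range may be too narrow for these data. Of the 2828 genes higher in untreated knockout 1838 fell with the agonist (533.7 expected for independent lists), and of the 2951 lower ones 1087 rose (316.9 expected), against 3 and 15 that changed further in the same direction. With 3 shared libraries the control group could not be split into 2 parts of at least 2 libraries, and part of the excess may come from them. The level of the 7 lists of other cells was 5.56 in untreated knockout, 3.82 in treated knockout and 2.84 in untreated wild type. Other cells in the untreated knockout libraries may therefore give part or all of the reversal, which was not tested. The genotype effects with and without agonist correlated at 0.61 ± 0.07 (Spearman 0.50), from separate libraries. Among the genes changed between untreated genotypes, the difference of treated knockout from untreated wild type was taken as a share of that of untreated knockout. Its median was 0.371 ± 0.094, and 0.967 in simulations without an agonist effect in knockout. That share was 0.228 for the genes higher and 0.526 for those lower in untreated knockout. It was 0.475 for the stem cell genes, 0.297 for B cell genes, 0.642 for erythroid genes and 0.835 for ageing genes. For ribosomal protein (−0.303), oxidative phosphorylation (−0.171) and autophagy and lysosome genes (−0.02) it was negative, so these medians lay past the untreated wild-type level. They cover only the 25, 35 and 11 members changed between untreated genotypes and carry no error. The level of the whole ribosomal protein list was 10 ± 0.48 in treated knockout and 9.65 ± 0.53 in untreated wild type (SD). For that list a passing of the wild-type level beyond the spread of libraries was not shown.

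**Figure D3:**
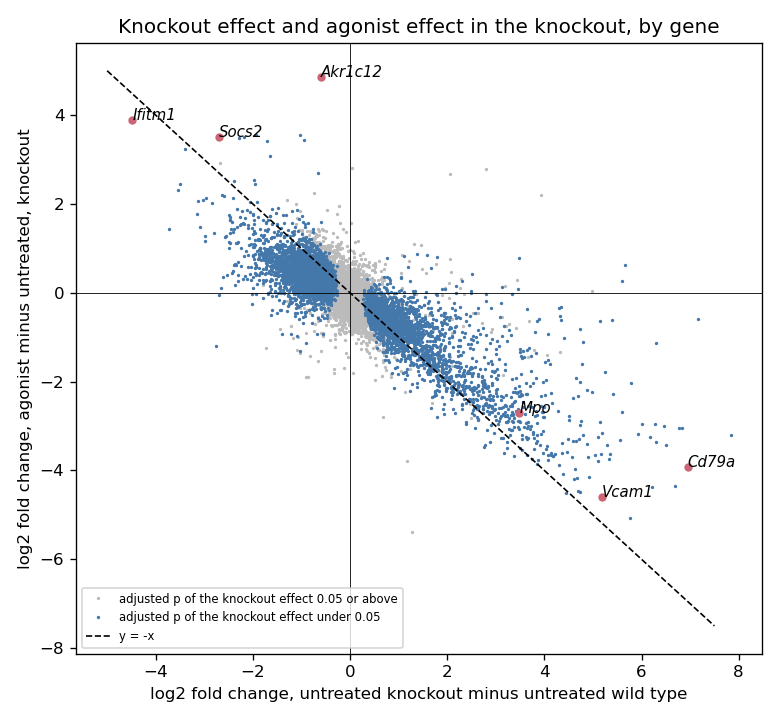
Each point is 1 of the 12823 genes tested, with the log2 fold change of untreated knockout against untreated wild type on the horizontal axis and that of treated against untreated knockout on the vertical axis, blue where the adjusted p on the horizontal axis was under 0.05. The dashed line marks equal and opposite changes, and Akr1c12 (4.85) lay away from it. The correlation was −0.83, against −0.50 in simulations of independent genes with the same shared libraries and no effect.

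The agonist effects in wild type and in knockout, which share no library, correlated weakly across genes, at 0.10 ± 0.07 (Spearman 0.02). The changed genes overlapped in 37 that rose in both (11.9 expected for independent lists) and 28 that fell in both (23.6 expected), against 14 and 17 in opposite directions (20.9 and 13.4 expected). Genes that rose in both included Akr1c12, Stxbp6, Podxl, Id1 (2.22 in wild type and 1.95 in knockout), Apoa1 (2.27 and 3.45) and Socs2. Genes that fell in both included Hmox1 (−2.88 and −3.65), the complement gene C1qb (−1.69 and −4.17), Gas6 (−1.92 and −2.79) and Csf3r (−1.31 and −1.55). For the agonist effect in wild type, the genotype effect was turned around, as untreated wild type minus untreated knockout. The 2 correlated at −0.22 ± 0.04 (Spearman −0.27, covariance −0.084), where a negative sign means changes in the direction of the knockout. The shared untreated wild-type libraries alone gave −0.50 and a covariance of −0.031. Of the genes changed between genotypes under the agonist, 76 of the 81 higher and 73 of the 95 lower ones had changed in the same direction without it (17.9 and 21.9 expected for independent lists), and 1 in the opposite one.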

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

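The tests of the retained shares of stem cell genes and of the erythroid genes against haemoglobin were chosen only after the result was seen, and the fits with a sex covariate and without the libraries of highest marker level were added after the data were seen.

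The difference between treated and untreated libraries was not the same in the 2 genotypes. The interaction term of the model passed for 1996 of the 12823 genes tested and 14 of 29 lists, with an estimated correlation for 0 of 29. In knockout, Y-linked genes averaged 11.3 to 24.9 FPKM in untreated and 0.01 to 0.04 in treated libraries, so sex enters the term. With a sex covariate it passed for 936 genes, and agonist and sex cannot be fully told apart. The level of the 7 lists of other cells was 5.56 in untreated and 3.82 in treated knockout. In wild type it was 2.84 untreated and 2.78 treated. Other cells in the untreated knockout libraries may therefore enter the term too, which was not tested. The difference in brackets is the log2 fold change of the agonist in knockout minus that in wild type. It was positive for Car1 (4.96), Ifitm1 (3.59), Erp27 (2.84), Lhcgr (2.72), Lbhd2 (2.70), Slc24a5 (2.55), Procr (2.53), Sult1a1 (2.52), Hacd4 (2.51) and Jam3 (2.47), in Car1 and Sult1a1 through the larger fall in wild type. The cytokine feedback genes Cish (2.39) and Socs2 (1.97), the stem cell gene Hlf (1.82), the cell cycle inhibitor Cdkn1c (1.48) and the platelet gene Vwf (1.45) were positive too. The neutrophil genes Ltf (−5.14), Fcnb (−4.44), Ngp (−4.24), Cd177 (−4.19), Cybb (−4.15), Camp (−3.98) and Mpo (−3.40) had a negative difference. So did the lymphoid gene Ly6d (−4.88), Id3 (−4.44), the adhesion gene Vcam1 (−3.93) and the integrin gene Itga2b (−1.43). Groups of 3 libraries were not tested for outliers.

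Other splits of the same libraries measured how often group labels without meaning give as many changed genes. The splits ignored the replicate numbers, and so the pairing hinted at in wild type. Among 100 splits of the agonist labels within genotype, 2 gave as many as the 1996 of the interaction, the real one included. The other one gave 2126 genes and exchanged the labels in a single genotype, so that it tested the sum of the effects. The highest of the rest gave 1701. The share argues against agonist labels without any meaning. Such splits also remove the agonist effect shared by both genotypes, so they cannot show that this effect differed between genotypes. For each of the 4 comparisons of a pair of groups, 1 of the 10 splits gave as many genes, the real one itself. The highest of the other splits gave 0 genes between untreated genotypes, 0 for the agonist in wild type, 8 for it in knockout and 2 between treated genotypes. The 10 splits are too few for a share under 0.05, so chance and group cannot be told apart by splits alone.

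Most markers of other blood and stromal cells were higher and most stem cell genes lower in untreated knockout, although no list passed with an estimated correlation, and cells of other types among the sorted ones may account for the former. At least 110 immunoglobulin variable segments reached 1 FPKM in each untreated knockout library, against at most 8 in an untreated wild-type one, as many B cell clones would give. The fallen stem cell genes kept between 4.5% (Ifitm1) and 57.3% (Gata2) of their wild-type level, more unequal than their errors (Q = 227 on 21 degrees of freedom), but the level of these genes in the added cells is in no table, so dilution as the whole cause and a change within stem cells cannot be told apart. The labels name no markers of the sorting gate, and a change of the stem cells themselves by loss of Thpo stays open and untested.

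Of 21 erythroid genes 9 were higher in knockout than in wild type under the agonist, in a list with an adjusted p of 0.318 with an estimated correlation. Without treated knockout replicate 1, where Car1 had 5804 FPKM, 9 erythroid members were higher, not all the same genes as with it, which argues against that library as the only source. Of the 7 called members other than Hba-a1 and Hba-a2, 1 (Car1) reached the higher of Hba-a1 and Hbb-bs in each treated knockout library. The other 6 did not and their level in red cells is in no table, so haemoglobin-rich red cells as the source and other sources cannot be told apart. Earlier erythroid progenitors among the sorted cells and an effect of the genotype stay open and were not tested.

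Sex differed between the treated groups, since all 3 treated knockout libraries carried Xist and 2 of the 3 treated wild-type libraries carried Y-linked RNA. With a sex covariate the 176 genes changed between treated genotypes kept a median 0.982 of their log2 fold change (quartiles 0.941 to 1.05), and 176 of 176 kept their sign, which argues against sex as the whole cause of the folds. The median error rose from 0.226 to 0.268 and the count fell to 38, because the covariate is partly confounded with the groups. An effect of the Thpo genotype stays open.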

How the results depend on the processing

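The sex covariate, the fit without the libraries of highest marker level and the blocked fit of wild type alone were chosen only after the data were seen. The named genes followed under the alternatives were the largest rises and falls of each contrast and the marker genes. Genes named only as list members were not followed gene by gene. Of the 2903 values of the genes followed, 2682 kept direction and side of the criterion. A further 148 were no longer past the criterion and 43 newly past it. The other 30 changed sign, in genes past the criterion in neither fit, and 0 called values reversed. These tallies leave out the size of the folds, which moved with the pseudocount for genes near the floor in 1 group, such as Ermap between treated genotypes (3.55 to 8.32). With an estimated correlation 0 lists passed in any of the 5 contrasts, so that every list call ended. At 2-fold 2252, 148, 1233 and 1170 genes changed between untreated genotypes, with agonist in wild type, with agonist in knockout and in the interaction. Groups did not overlap for 3442 genes with agonist in wild type and 3221 between treated genotypes. The latter comparison gave 326 genes at a pseudocount of 0.1, 57 without a filter, with 26521 genes tested, and 270 under quantile normalization, and the agonist in wild type 122 with a filter at 5 FPKM, with 9487 genes tested. With only the groups compared in the fit the counts were 628 (agonist in wild type), 2021 (agonist in knockout) and 57 (treated genotypes). Array weights, whose estimation stopped before convergence, gave 2488, 7138, 4327 and 6220 for these 3 and the interaction. A sex covariate gave 1609 for the agonist in knockout, 38 for treated genotypes and 936 for the interaction. Without the libraries of highest marker level treated genotypes gave 1712, and the correlations of genotype effects and of reversal were 0.538 and −0.754. That of the agonist in wild type with the untreated difference of wild type minus knockout was −0.176 at a pseudocount of 0.1. Unless stated, the cause was not tested.

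Leaving out 1 library gave 65 to 156 genes for the agonist in wild type, 2368 to 4308 for it in knockout, 31 to 1559 for treated genotypes (7 to 18 lists) and 1088 to 2687 for the interaction. The median of ribosomal proteins with agonist in wild type ranged from −0.096 to 0.410, and the direction of its test reversed without untreated replicate 1. Immediate early genes there ranged from −0.751 to 0.154, with the test reversed without untreated replicate 3. Ribosomal proteins between treated genotypes ranged from −0.053 to 0.420, with a negative median without treated knockout replicate 1, where the test reversed, and without treated wild-type replicate 1 (−0.024, adjusted p = 0.216). The replicate number as a block in the fit of all 12 libraries gave 5788, 199, 3787, 174 and 1922 genes for the 5 contrasts. Under it 6 calls of the genes in the tally and 0 calls of lists were lost. For the agonist in wild type, where the data hint at pairing by number, the lost gene calls were Hspa1a and Hspa1b. Of all 236 calls of that contrast, 176 remained with the block, and genes named only as list members were not followed. In the wild-type groups alone the block gave 864 genes against 628 without it. In knockout the same-numbered libraries correlated at 0.19, 0.06 and 0.19, each best with its own number in 6 of 6 cases, a hint from the data and not the design. Depth limits values near 0.04 to 0.05 FPKM, such as those of Thpo.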

Other observations

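The gene families were singled out only after their values were seen, and the tests of their members are those of the contrasts planned. The agonist raised a cluster of aldo-keto reductase genes on chromosome 13 in both genotypes. All 3 tested genes of the Akr1c family rose, Akr1c12 by 4.78 in wild type and 4.85 in knockout, Akr1c13 by 2.03 and 3.09 and Akr1c19 by 2.04 and 3.43 (log2 fold change). Akr1c13 had 196 FPKM in untreated and 795 in treated wild type, 61.3 in untreated and 551 in treated knockout. Akr1c13 and Akr1c19 were lower in untreated knockout than in untreated wild type (−1.65 and −1.70). The genes are close paralogs, so that reads may be shared between them, and the directions were the same under the 3 scalings. Akr1c12 kept its call in all 18 alternatives, with a log2 fold change of 4.78 in the fit of wild-type libraries with the replicate block.

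Interferon-induced membrane protein genes of the Ifitm family changed in both directions in untreated knockout. Of 6 tested, Ifitm1 (−4.48), Ifitm3 (−2.40), Ifitm7 (−1.73) and Ifitm2 (−1.52) fell in untreated knockout, and they rose with the agonist there by 3.89, 2.14, 0.53 and 1.05. None of the 6 rose with the agonist in wild type, where Ifitm7 fell by 0.90 (adjusted p = 0.0302). Ifitm6 (2.77) and Ifitm10 (1.06) were higher in untreated knockout, where myeloid genes were higher as well.

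Untreated knockout replicates 1 and 3 carried Y-linked RNA (mean 14.7 and 11.3 FPKM) together with Xist (4.91 and 8.70 FPKM). The other 10 libraries carried one or the other, with Xist at 20.1 to 41.3 FPKM beside Y-linked RNA of at most 0.14, or Y-linked RNA at 18.5 to 24.9 FPKM beside Xist of at most 0.20.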
